A study of Homo sapiens with 4 samples.

How the data were processed

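RNA from MDA-MB-231 cells, an established human breast cancer line with a mesenchymal-like appearance, was measured on Illumina HumanHT-12 v4 bead arrays. Per the labels, 2 arrays held cells transduced with a scrambled short hairpin RNA (shCntrl) and 2 arrays held cells transduced with a hairpin against TRPM7 (shT7#1). Samples were grouped by the transduction stated in the labels. The labels number the arrays of each group 1 and 2 and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Array positions, slides and scan batches were not given in the sources used here and were not modelled.

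The deposited table of unnormalised data gave 1 signal intensity per probe and array on a linear scale, with no sign of background subtraction in the values. The same deposited table gave a detection p-value for each probe on each array, which compares the signal with that of negative control beads. GenomeStudio 2011.1 is named in the submitters' processing notes. A second deposited table held the authors' processed log2 values, 1 per gene symbol. Per the file headers, the authors normalised with RMA in ArrayStar on a log2 scale. How the authors joined several probes of a gene was not given in the sources used here. The medians of the authors' 4 columns lay between 3.02 and 3.03, and the columns showed no centring of genes. A further deposited table gave the authors' mean log2 value of each group and a linear fold ratio of shT7#1 over shCntrl. Per the file headers, the authors had removed genes under a log2 value of 2.5 in both groups from that table. The authors' fold table holds no error and was used only for comparison.

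The intensities were processed here with limma 3.58.1 in R 4.3.3. Background was corrected by a normexp fit to the negative control level, inferred from the detection p-values, with an offset of 16. Quantile normalisation and a log2 transform followed. A probe entered the tests if its detection p was below 0.05 on at least 2 of the 4 arrays. Of the 47323 probes, 20366 passed, of which 19326 carried a gene symbol. A gene was represented by its brightest passing probe, which gave 14731 genes. Another detected probe existed for 251 of the called genes, and in 20 of these it changed in the opposite direction. In 1 of them the other probe passed the threshold in the opposite direction.

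Gene symbols came from the deposited table and were updated through a RefSeq gene table of the assembly GRCh38.p14, which served only for names and for the order of neighbouring genes. Of the 31426 symbols, 17761 were current, 3297 were updated and 10368 matched no entry and were kept as given. A spreadsheet had turned 23 symbols into dates, and these probes were left out of the gene tests. A further 3270 probes had no symbol.

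The main comparison was shT7#1 against shCntrl, fitted with limma (lmFit and eBayes, default settings) on all 4 arrays with the group as the only term. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and borrowed 3.66 from the other genes. Errors of log2 changes are standard errors from this fit, and errors of group means are standard deviations over 2 arrays. A probe not above background on either array of a group has only a bound there. Its change was given as "at least N-fold", from the mean of the bright group against the higher of the detection floor and the probe's own signal on each dim array. The detection floor was the lowest normalised signal among probes above background, between 4.92 and 4.98 log2 units per array. Only 4 arrays limit the precision of every value.

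Before the data were examined, 29 gene lists of 681 distinct genes were fixed, together with the test, the alternatives and the rule for naming genes. Of the list genes, 677 had a probe and 580 were tested. The lists covered mesenchymal, epithelial and SOX4-linked genes, TGF-beta response, YAP/TAZ and SRF/MRTF targets, actomyosin contractility, focal adhesions, extracellular matrix, and ion channels and carriers. They also covered metallothioneins, interferon and NF-kB targets, cell cycle, p53 targets, unfolded protein response, lipid synthesis, hypoxia, respiratory chain, ribosomal proteins, histones, immediate early genes, axon guidance, autophagy and small RNA machinery. Fibroblast, leukocyte, luminal breast and endothelial markers served as lists of other cell types. Each list with at least 5 tested members was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 28 lists. Camera with an estimated correlation and fry were run as alternatives. With 2 residual degrees of freedom the estimated correlation is imprecise, and the test that uses it has only these 2 degrees of freedom.

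The genes named are TRPM7, SOX4, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, and up to 4 members of each list. List members are those past the threshold with the largest change, or the 2 with the largest change where none passed. Some genes that this rule selects are not reported here. Named outside this rule, after their values were seen, were CXCL3, LIF, CCL2, NFKB1, PTGS2, NFKBIA, TNFAIP3, IL6, IFITM1, SNAI2, VIM, CDH2, CDH1, SLC30A1, MTF1, IL11, CD14, LAPTM5, ESR1, FOXA1 and FLVCR1, and the genes of the closing observations that are said to be so. TRPM7 was given as a value without a test because its probe did not pass the detection filter.

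The procedure was tested on simulated data built from the values of these arrays. In 5 simulations over 14731 genes with known changes, 1 of 335 changed genes (0.299%) was called at a log2 size of 0.5. At a log2 size of 1, 130 of 335 (38.8%) were called, and at a log2 size of 2, 306 of 330 (92.7%). Of 465 calls, 28 (6.02%) were genes without a simulated change. Each simulation changed fewer genes than the 957 called in the data. The Benjamini-Hochberg threshold is stricter when fewer genes change. The shares of changed genes called may therefore be lower than they would be in the data. With nothing changed, 0 of 560 list tests were called. A list shifted by 0.5 log2 units was called in 20 of 20 simulations with the preset correlation and in 0 of 20 with the estimated one. Genes were drawn independently of each other in these simulations. The list results therefore do not test how often correlated genes give false list calls at the preset correlation.

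Alternatives were median scaling, cyclic loess, no background correction, the authors' processed values, no detection filter, detection on all 4 arrays, an intensity trend in the variance prior, every probe tested on its own, a 2-fold minimum, a looser threshold, a replicate block and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used here, and no coordinates are given.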

Results

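Gene expression was measured in MDA-MB-231 breast cancer cells carrying a scrambled hairpin (shCntrl, n = 2 arrays) or a hairpin against TRPM7 (shT7#1, n = 2 arrays). TRPM7 encodes a channel for divalent cations fused to a kinase domain. The series title concerns the part of TRPM7 in the mesenchymal state of these cells, through tension and the transcription factor SOX4. The arrays held 47323 probes each. On the shCntrl arrays 19779 and 20261 probes were above background, and on the shT7#1 arrays 19492 and 19938. The median signal lay between 117.6 and 125.4 units, and the highest signal lay between 20673 and 22137. Log2 values of the 14731 tested genes, each at its brightest passing probe, correlated at 0.994 between the shCntrl arrays and 0.993 between the shT7#1 arrays. Correlations across the groups were lower, between 0.982 and 0.984. No probe had identical signals on a pair of replicate arrays.

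TRPM7 itself could not be followed on these arrays. Its single probe was not above background on any of the 4 arrays, with detection p-values of 0.275 and 0.443 in shCntrl and 0.529 and 0.331 in shT7#1. The log2 signal was 4.56 ± 0.06 (SD, n = 2) in shCntrl and 4.52 ± 0.06 (SD, n = 2) in shT7#1. Both means lay under the detection floor, so no fold change was computed. The authors' deposited table lists TRPM7 at 0.91-fold in shT7#1. The arrays therefore gave no check of the knockdown, and the arrays labelled shT7#1 were taken as such from the labels.

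SOX4, a transcription factor of the SRY-box family, fell 4.35-fold in shT7#1. Its log2 signal was 8.06 ± 0.10 (SD, n = 2) in shCntrl and 5.93 ± 0.06 (SD, n = 2) in shT7#1. The log2 change was -2.12 ± 0.12 (SE), with a limma adjusted p of 0.00218. The authors' deposited table gives SOX4 at 0.17-fold. Of the 13 tested genes linked to SOX4, 0 rose, 1 fell and 12 were not called over all genes tested. Adjusted over the list alone, 1 was higher and 2 were lower. The gene that fell was AXIN2, a feedback inhibitor of Wnt signalling, at -0.93 ± 0.17 log2 units (SE). The list as a whole was not called, with a camera adjusted p of 0.357.

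**Figure D1:**
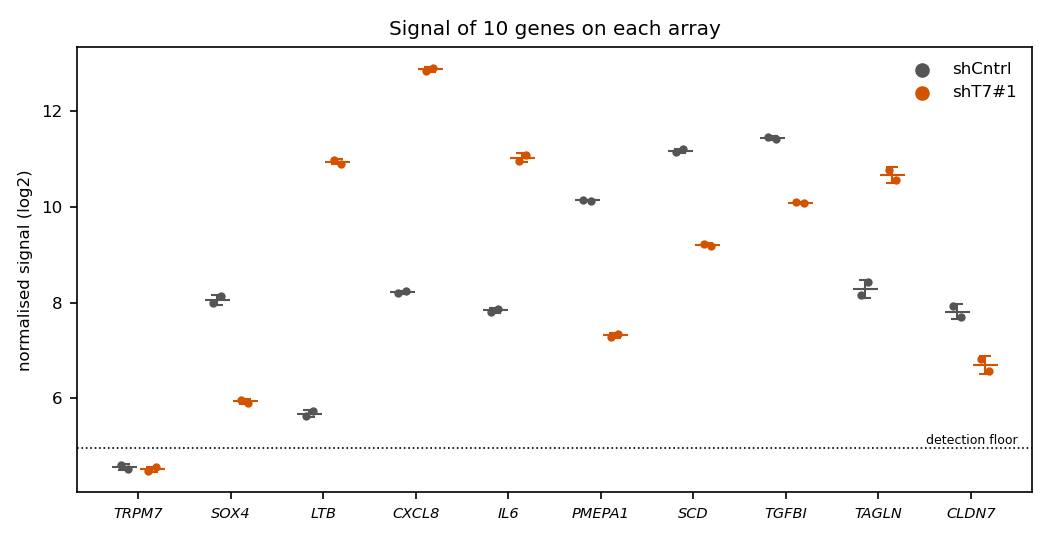
Normalised log2 signal (vertical axis) of 10 genes on each array, with grey points for shCntrl and orange points for shT7#1. Points are single arrays, horizontal bars are group means, whiskers are the SD over 2 arrays, and the dotted line is the mean detection floor. TRPM7 lies under the floor in both groups, SOX4 drops from 8.06 to 5.93, and CXCL8 climbs from 8.21 to 12.87.

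The largest increase in shT7#1 was that of LTB and the largest decrease above background on all 4 arrays was that of PMEPA1. Over the 14731 genes tested, 434 were higher and 523 were lower in shT7#1. Changes of at least 2-fold were found for 162 of the higher and 168 of the lower genes. In all 957 called genes both arrays of a group lay on the same side of both arrays of the other group. Such a separation was found for 55.7% of the tested genes, where chance gives 33.3%. Of the higher genes, 52 were not above background on either shCntrl array. Of the lower genes, 43 were not above background on either shT7#1 array. Leaving out any 1 of the 4 arrays reduced the counts to between 69 and 86 higher and between 38 and 53 lower genes. With all 4 arrays the counts ranged from 115 higher and 104 lower on the authors' processed values to 1161 higher and 1262 lower without background correction.

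The 12 largest increases included chemokine, cytokine and acute-phase genes. LTB, which encodes lymphotoxin beta, rose 38.5-fold, a log2 change of 5.27 ± 0.12 (SE) with a limma adjusted p of 0.000239. Its second probe, not above background on either shCntrl array, had a fitted change of 4.39. The neutrophil chemokines CXCL1 and CXCL8 rose by 4.91 ± 0.19 and 4.66 ± 0.11 log2 units (SE). CXCL2 rose by a fitted 3.79 log2 units but was above background on only 1 shCntrl array, so the size of its change is uncertain. The acute-phase genes SAA1 and SAA2 rose by 4.07 and 4.02 log2 units, and their near-identical sequences may share signal. Other SAA1 probes had fitted changes of 3.50 and 2.73, and SAA2 lay near the detection floor in shCntrl, at 5.07. CSF2, which encodes the growth factor GM-CSF, rose by 3.77 log2 units. LTA, which encodes lymphotoxin alpha, rose by 3.71 log2 units, and PTX3, a long pentraxin, by 3.65. NPPB, IL1A and EBI3 were not above background on either shCntrl array and were at least 8.11-fold, 8.93-fold and 9.41-fold higher. The limma adjusted p of these 12 genes lay between 0.000239 and 0.00282. The authors' deposited table gives larger folds for LTB and CXCL1, at 74.46 and 53.51.

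Among the 12 largest decreases, LIPG, which encodes endothelial lipase, was not above background on either shT7#1 array and was at least 7.44-fold lower. That bound holds for its brightest probe only. A second LIPG probe, also not above background on either shT7#1 array, had a smaller fitted change of -1.81 log2 units. The uncharacterised locus LOC100134294 was at least 7.71-fold lower. PMEPA1, a TGF-beta target that restrains SMAD signalling, fell 7.07-fold, a log2 change of -2.82 ± 0.11 (SE) with a limma adjusted p of 0.000733. Another probe above background on all 4 arrays changed by -2.08. TCN1, a vitamin B12 binding protein, changed by a fitted -2.15 log2 units but was above background on only 1 shT7#1 array, so the size of its change is uncertain. SCD, which encodes stearoyl-CoA desaturase, changed by -1.96 ± 0.11. CCND2, which encodes cyclin D2, was not above background on either shT7#1 array and was at least 3.23-fold lower at its brightest probe. A second CCND2 probe, also not above background on either shT7#1 array, had a smaller fitted change of -1.07 log2 units. The remaining members of the 12 were SOX4, LOC731486 at -1.87, KRT81 at -1.79, the mitochondrial carrier SLC25A23 at -1.79, the sodium channel subunit SCNN1A at -1.78 and HN1 at -1.75 log2 units. The limma adjusted p of these 12 genes lay between 0.000733 and 0.00708. Hair keratin probes such as that of KRT81 can bind transcripts of close relatives.

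**Figure D2:**
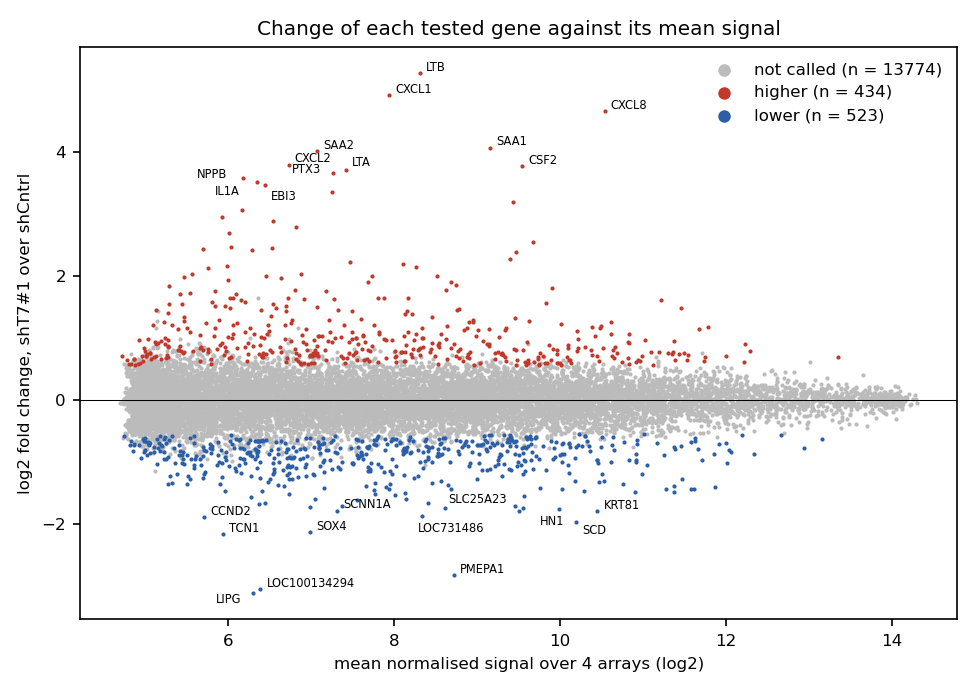
Log2 fold change of each tested gene, shT7#1 over shCntrl (vertical axis), against its mean normalised log2 signal over 4 arrays (horizontal axis). Red points are the 434 genes called higher, blue points the 523 called lower and grey points the genes not called. Genes not above background in a group are drawn at their fitted value, and among the labelled genes above background on all 4 arrays the extremes are LTB at 5.27 and PMEPA1 at -2.82.

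The list of genes driven by the transcription factor NF-kB was called higher at the preset correlation but not with an estimated one. Of 25 tested members of this list, 20 rose, 0 fell and 5 were not called over all genes tested. Counts adjusted over the list alone were 21 higher and 0 lower. The median log2 change was 2.00, and the camera adjusted p was 1.82e-22. With an estimated correlation of -0.039, below the preset 0.01, the camera adjusted p was 0.219. Besides CXCL1, CXCL8, CXCL2 and CSF2, the list held the inhibitors NFKBIA and TNFAIP3, which rose by 1.14 and 2.45 log2 units. IL6 rose by 3.19 ± 0.12 log2 units (SE). The members not called were CXCL3, LIF, CCL2, NFKB1 and PTGS2. Chemokine genes of the CXCL1 group are close paralogs.

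The list of interferon-stimulated genes was called higher at the preset correlation but not with an estimated one. Of 33 tested members, 13 rose, 1 fell and 19 were not called over all genes tested. Adjusted over the list alone, 15 were higher and 1 was lower. RSAD2 (viperin) rose by 1.23 ± 0.13 log2 units (SE), ISG20 by 1.12, IFIT3 by 1.06 and the RNA sensor RIGI by 0.97. The gene that fell was IFITM1, at -0.85 log2 units. The list median was 0.32 log2 units and the camera adjusted p was 7.53e-05, against adjusted p = 0.486 with an estimated correlation.

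Lipid synthesis genes were called lower as a list at the preset correlation. Of 30 tested genes of cholesterol and fatty acid synthesis, 0 rose, 7 fell and 23 were not called over all genes tested. Counts adjusted over the list alone were 0 higher and 9 lower. Besides SCD, the members that fell included ACLY, which makes cytosolic acetyl-CoA, at -0.97 ± 0.13 log2 units (SE) and the desaturase FADS1 at -0.96. The median was -0.29 and the camera adjusted p was 0.000165, against adjusted p = 0.514 with an estimated correlation.

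Genes of hypoxia and glycolysis were called lower as a list at the preset correlation. Of 27 tested members, 1 rose, 5 fell and 21 were not called over all genes tested. Adjusted over the list alone, 1 was higher and 9 were lower. ANGPTL4 changed by -1.34 ± 0.13 log2 units (SE), but its other detected probes changed by -0.06 and 0.20. The glycolytic regulator PFKFB4 changed by -1.31 and the mitophagy receptor BNIP3L by -0.94, with -0.54 at its second probe. ADM, which encodes adrenomedullin, rose by 1.48 log2 units. The median was -0.24 and the camera adjusted p was 0.000630, against adjusted p = 0.651 with an estimated correlation.

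The list of autophagy and lysosome genes was called lower only at the preset correlation of camera, with an adjusted p of 0.0208 against 0.651 with an estimated correlation. The median was -0.23 log2 units. Of 24 tested members, 0 rose, 4 fell and 20 were not called over all genes tested. Counts adjusted over the list alone were 1 higher and 6 lower. The members that fell were BECN1 at -0.97 ± 0.13 log2 units (SE), the cathepsins CTSD at -0.91 and CTSB at -0.72, and MAP1LC3B at -0.73. Over 12 alternatives the camera adjusted p at the preset correlation lay between 0.000805 and 0.226, the highest without shT7#1 replicate 2.

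The list of metallothioneins, small zinc-binding proteins, was called lower at the preset correlation although no single member passed. It also held the zinc exporter SLC30A1, at 0.28 log2 units, and the metal-responsive transcription factor MTF1, at 0.01. Of 10 tested members, these included, 0 rose, 0 fell and 10 were not called by limma over all genes tested, while 7 had an unadjusted p under 0.05. Adjusted over the list alone, 0 were higher and 5 were lower. MT1G lay at -0.75 ± 0.18 log2 units (SE), with an adjusted p of 0.0739, and was above background in both groups. MT1H was not above background on either shT7#1 array, so its difference is bounded at 1.20-fold or more, with an adjusted p of 0.0552. The median was -0.41 and the camera adjusted p was 0.0119, against adjusted p = 0.651 with an estimated correlation. Over 12 alternatives it lay between 0.000699 and 0.0768, the highest without shCntrl replicate 1. Metallothionein probes can bind several members of the family.

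**Figure D3:**
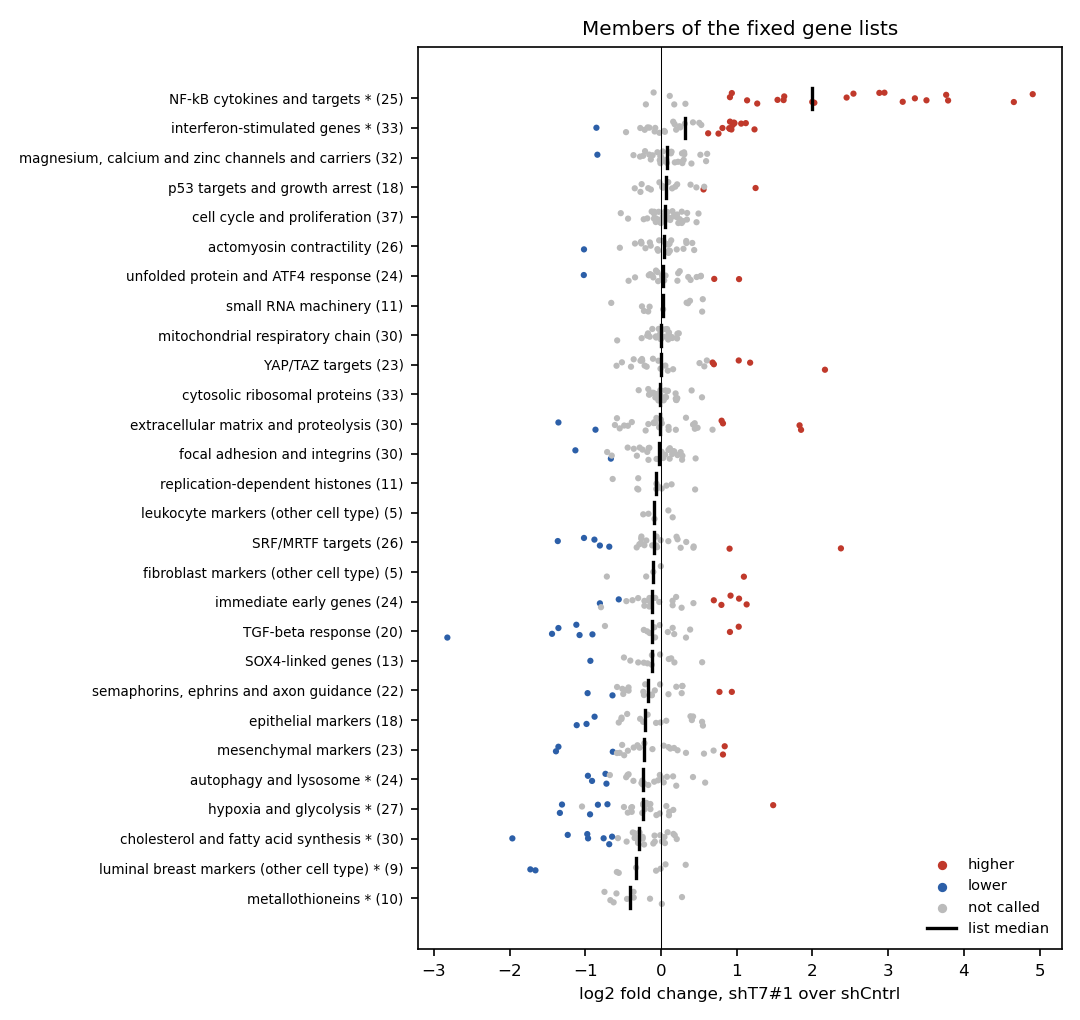
Log2 fold change, shT7#1 over shCntrl (horizontal axis), of every tested member of the 28 tested gene lists (vertical axis, number tested in parentheses). Points are genes, red higher, blue lower and grey not called, black bars are list medians, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The NF-kB list stands apart with a median of 2.00, and the other medians lie between -0.41 and 0.32.

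Mesenchymal markers changed singly and in both directions. Of 23 tested members, 2 rose, 3 fell and 18 were not called over all genes tested. Counts adjusted over the list alone were 4 higher and 7 lower. The matrix genes COL6A3 and TGFBI fell, at -1.39 ± 0.12 and -1.35 ± 0.11 log2 units (SE). The transcription factor SNAI2 fell by 0.64 log2 units, with a limma adjusted p of 0.0434. COL6A2 rose by 0.82 log2 units, with a limma adjusted p of 0.0485, while its other detected probes had fitted changes of 0.71 and 0.12. COL5A2, not above background on either shCntrl array, was at least 1.38-fold higher. VIM, which encodes vimentin, lay at -0.28 and CDH2, which encodes N-cadherin, at 0.69 log2 units, and neither passed. The median was -0.22 and the camera adjusted p was 0.335.

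Epithelial markers were not called as a list either, and the members that passed fell. Of 18 tested members, 0 rose, 3 fell and 15 were not called over all genes tested. Adjusted over the list alone, 1 was higher and 6 were lower. CLDN7, a tight junction claudin, changed by -1.11 ± 0.15 log2 units (SE) and the keratin KRT7 by -0.98. CDH1, which encodes E-cadherin, was not above background on any array. The median was -0.21 and the camera adjusted p was 0.179. Over 12 alternatives it lay between 0.0345 and 0.353, the lowest where detection on all 4 arrays was required.

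Luminal breast markers, kept as a list of another cell type, were called lower as a list at the preset correlation. Of 9 tested members, 3 of which are keratins shared with the epithelial list, 0 rose, 2 fell and 7 were not called over all genes tested. Counts adjusted over the list alone were 0 higher and 4 lower. The transcription factor SPDEF changed by -1.73 ± 0.16 log2 units (SE). AGR2, a protein disulfide isomerase of secretory cells, changed by -1.66 ± 0.13, while its second probe, near background, changed by -0.14. The median was -0.33 and the camera adjusted p was 0.0312, against adjusted p = 0.651 with an estimated correlation. Over 12 alternatives it lay between 0.0194 and 0.0825, and the call was lost without a detection filter (0.0785), without shCntrl replicate 2 (0.0718) and without shT7#1 replicate 2 (0.0825).

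Genes of the TGF-beta response moved in both directions. Of 20 tested members, 2 rose, 6 fell and 12 were not called over all genes tested. The counts adjusted over the list alone were also 2 and 6. Besides PMEPA1 and TGFBI, the transcriptional regulators BHLHE40 and ID1 fell, at -1.44 ± 0.11 and -1.12 ± 0.12 log2 units (SE). The ligand gene TGFB2 rose by 1.03 log2 units and IL11 by 0.91. The median was -0.12 and the camera adjusted p was 0.134. Over 12 alternatives it lay between 0.0262 and 0.353, under the threshold without a detection filter (0.0262) and without shT7#1 replicate 1 (0.0413). By fry, which does not compare the list with other genes, the adjusted p was 0.0204.

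The series title names tension, which transcript levels do not measure. The lists tied to contractility and mechanical signalling were not called by camera, which tests for a shift of a list in 1 direction. Of 26 tested actomyosin genes, 0 rose, 1 fell and 25 were not called over all genes tested, and adjusted over the list alone the counts were also 0 and 1. The gene that fell was TPM4, which encodes a tropomyosin, at -1.02 ± 0.14 log2 units (SE). The camera adjusted p was 0.997. Of 26 tested targets of SRF and its cofactor MRTF, 2 rose, 5 fell and 19 were not called over all genes tested, and adjusted over the list alone 4 were higher and 5 were lower. TAGLN, which encodes transgelin, rose by 2.38 ± 0.15 log2 units (SE) and FHL1 by 0.91, while FILIP1L changed by -1.36. By camera the list had an adjusted p of 0.419. Of 23 tested targets of YAP and TAZ, 5 rose, 0 fell and 18 were not called over all genes tested, and adjusted over the list alone 8 were higher and 2 were lower. The kinase gene NUAK2 rose by a fitted 2.17 log2 units but was above background on only 1 shCntrl array, so the size of its change is uncertain. The coagulation factor gene F3 rose by 1.18 and IGFBP3 by 0.70. The camera adjusted p was 0.381, and the median of -0.01 differed in sign from the mean of 0.20.

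Adhesion and matrix genes changed singly. Of 30 tested focal adhesion and integrin genes, 0 rose, 2 fell and 28 were not called over all genes tested, and adjusted over the list alone 0 were higher and 4 were lower. The integrin genes that fell were ITGA2 at -1.13 ± 0.11 log2 units (SE) and ITGB5 at -0.66. By camera the list had an adjusted p of 0.357. Of 30 tested extracellular matrix and proteolysis genes, 4 rose, 2 fell and 24 were not called over all genes tested, and adjusted over the list alone 6 were higher and 5 were lower. MMP9, which encodes a gelatinase, was not above background on either shCntrl array and was at least 2.41-fold higher. The protease inhibitor gene TIMP3 changed by -0.87. The camera adjusted p was 0.826.

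Ion handling, growth and stress lists were not called either. Of 32 tested magnesium, calcium and zinc channels and carriers, 0 rose, 1 fell and 31 were not called over all genes tested, with the same counts of 0 and 1 adjusted over the list alone. ORAI3, a calcium channel subunit, was not above background on either shT7#1 array and was at least 1.61-fold lower. By camera the list had an adjusted p of 0.335. Of 37 tested cell cycle genes, limma called 0 over all genes tested and 0 adjusted over the list alone, and 6 had an unadjusted p under 0.05. MCM2 lay at -0.53 and CDT1 at 0.50 log2 units, and the camera adjusted p was 0.351. Of 18 tested p53 targets, 2 rose, 0 fell and 16 were not called over all genes tested, with 2 higher and 0 lower adjusted over the list alone. PLK2 rose by 1.25 ± 0.13 log2 units (SE) and CDKN1A, an inhibitor of cyclin-dependent kinases, by 0.56, and the camera adjusted p was 0.351. Of 24 tested genes of the unfolded protein and ATF4 response, 2 rose, 1 fell and 21 were not called over all genes tested, with 3 higher and 1 lower adjusted over the list alone. ATF3 rose by 1.03 log2 units and DNAJB9 by 0.70, DDIT4 fell by 1.02 log2 units, and the camera adjusted p was 0.358.

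Immediate early and guidance genes showed single changes in both directions. Of 24 tested immediate early genes, 5 rose, 2 fell and 17 were not called over all genes tested, with 6 higher and 3 lower adjusted over the list alone. Besides ATF3, KLF4 rose by 1.13 and DUSP5 by 0.92 log2 units, and FOS, not above background on either shT7#1 array, was at least 1.36-fold lower. The camera adjusted p was 0.997. Of 22 tested semaphorin, ephrin and axon guidance genes, 2 rose, 2 fell and 18 were not called over all genes tested, with 2 higher and 6 lower adjusted over the list alone. The semaphorin receptor NRP1 changed by -0.97 ± 0.13 log2 units (SE), but its second probe, above background on all 4 arrays, changed by -0.32. EPHA4 changed by -0.64, while EFNA1 rose by 0.94 and SLIT2 by 0.77. By camera the list had an adjusted p of 0.335.

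In the housekeeping lists limma called 0 genes over all genes tested. Among 30 respiratory chain genes 0 had an unadjusted p under 0.05, and NDUFS1 lay at -0.58 ± 0.41 log2 units (SE) and UQCRC1 at -0.26. Among 33 ribosomal protein genes 3 had an unadjusted p under 0.05, with RPS7 at 0.54 and RPL8 at 0.40. Among 11 histone genes 3 had an unadjusted p under 0.05, with H3C10, above background on only 1 shT7#1 array, at -0.64 and H4C14 at 0.45. Among 11 genes of the small RNA machinery 5 had an unadjusted p under 0.05, with TNRC6B at -0.66 and XPO5 at 0.55. Adjusted over the list alone, 2 genes of the small RNA machinery were higher and 0 genes of the other 3 lists changed. The camera adjusted p of these lists was 0.826, 0.801, 0.609 and 0.609.

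Few markers of leukocytes, fibroblasts and endothelium passed the detection filter. Of 5 tested leukocyte markers, limma called 0 over all genes tested and 0 adjusted over the list alone, and 0 had an unadjusted p under 0.05. HLA-DRA lay at -0.23 and CD68 at -0.17 log2 units, and the camera adjusted p was 0.826. Of 5 tested fibroblast markers, 1 rose, 0 fell and 4 were not called over all genes tested, with 1 higher and 1 lower adjusted over the list alone. The gene that rose was PI16, by 1.09 ± 0.13 log2 units (SE), and the camera adjusted p was 0.850. Only 2 endothelial markers were tested, PECAM1, above background on only 1 shT7#1 array, at -0.40 and ESAM at -0.04 log2 units, and 0 passed by limma. That list was too short for a list test.

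Across the 28 lists tested, camera called 2 higher and 5 lower at the preset correlation. With an estimated correlation 0 lists were called, and 2 had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for the NF-kB (-0.039), interferon (-0.014) and luminal (-0.114) lists. Those calls were thus not lost to a higher correlation. For lipid synthesis the estimate was 0.0147, close to the preset. For hypoxia and glycolysis, autophagy and lysosome genes and metallothioneins it was 0.130, 0.172 and 0.645. The test with an estimated correlation has only 2 degrees of freedom. In the simulations it called a list shifted by 0.5 log2 units in 0 of 20 runs. A list that it does not call is therefore left undecided by that test. By fry the adjusted p was 0.00314 for the NF-kB list, 0.0169 for interferon-stimulated genes, 0.0294 for lipid synthesis and 0.0162 for luminal markers. These calls were kept. The fry adjusted p was 0.0921 for hypoxia and glycolysis, 0.103 for autophagy and lysosome genes and 0.177 for metallothioneins, so these calls were lost. In 6 lists the median, mean and test differed in sign.

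The authors' deposited table was compared with these values through 14538 shared genes. Of 430 shared genes called higher here, 427 lay above 1-fold in the authors' deposited table and 224 at 2-fold or more. Of 518 called lower here, 517 lay below 1-fold in the authors' deposited table and 244 at 2-fold or more. The log2 fold changes of both sources correlated at 0.920 across genes, which are not independent replicates.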

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

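Probes without a usable gene symbol, including any whose symbol had become a date, were left out of the gene tests. Some of them carried a signal above background that differed between the groups. Of 1040 such probes above background on at least 2 arrays, limma called 10 higher and 22 lower in shT7#1. Their genes were not named here, and no explanation was tested. No group held enough arrays for a search for single outlying arrays.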

How the results depend on the processing

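Of the single genes, SOX4 stayed lower and past the threshold under every alternative that tested it. The 24 genes with the largest changes kept their direction under every alternative in which they were tested. Of these, 23 passed on the authors' processed values, without shCntrl replicate 1 and without shCntrl replicate 2, and 16 were tested where detection on all 4 arrays was required. Of 77 named genes called here, 40 kept their call on the authors' processed values and between 31 and 34 with 1 array left out, and 0 reversed. The counts of genes moved more. They were 1161 higher and 1262 lower without background correction, 115 and 104 on the authors' processed values, 699 and 818 with detection on all 4 arrays, and 1137 and 1254 with an intensity trend in the variance prior. A 2-fold minimum left 162 and 168, and an adjusted p under 0.10 gave 971 genes higher and 1114 genes lower. Leaving out 1 array gave between 69 and 86 higher and between 38 and 53 lower genes. The counts were 74 and 53 without shCntrl replicate 1, 86 and 47 without shCntrl replicate 2, 69 and 44 without shT7#1 replicate 1, and 74 and 38 without shT7#1 replicate 2. The remaining array of a group was then assumed to vary like the other group, and the fit had fewer arrays. For the other settings the cause was not tested. Same-numbered arrays deviated together only weakly (r = 0.125 across genes), and with 2 pairs the numbers were not taken to pair the samples. With the replicate number as a block the counts were 563 and 676, and 947 of the 957 calls were shared. TRPM7 was under the detection floor here and has no fold change, and the authors' processed values of it differed by -0.14 log2 units. For the lists, 0 were called higher and 0 lower with an estimated correlation. By fry the NF-kB and interferon lists were called higher and 3 lists lower. The 3 were lipid synthesis, luminal markers and the TGF-beta response, the last of which was not called in the main list test. With 1 array left out, between 3 and 6 lists were called lower, with 3 without shT7#1 replicate 2. The NF-kB list kept its call in 12 of 12 alternatives of the values, with medians between 1.13 and 2.22. A slide block was not run because no slide was given in the sources used here. Signals near background limit the folds of dim genes.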

Other observations

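The tests of leukocyte RNA, of interferon as the whole source, and of both explanations for the luminal fall were chosen only after the values they use had been seen. Genes in the next 3 paragraphs were also chosen after their values were seen, and each was called by limma.

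Single genes outside the fixed lists were picked because they rose, with no count of related genes that did not. The adaptor gene TRAF1 rose by 2.02 log2 units, and CD83, a surface marker of activated immune cells, by 1.89. The receptor gene TNFRSF9 rose by 1.61, the inhibitor gene NFKBIE by 1.45 and the nuclear inhibitor gene NFKBIZ by 1.38. IKBKE, an interferon-linked kinase gene, rose by 1.29 and the inhibitor TNIP1 by 1.11.

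Further single genes were picked because they rose, and junction genes were not counted as a group. CLDN1, which encodes the tight junction protein claudin 1, rose by 2.78 ± 0.13 log2 units (SE), with a limma adjusted p of 0.000982. The adhesion gene MPZL2 rose by 1.97 log2 units, and CGNL1, which encodes a junction protein of the cingulin family, by 0.72. TRIM29 was not above background on either shCntrl array and was at least 3.67-fold higher. CLDN7 of the fixed epithelial list went the other way, at -1.11.

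Other single genes were picked because they fell, again with no count of related genes. The lipoxygenase gene ALOX5 changed by -1.57 log2 units, its partner ALOX5AP by -1.35 and the thromboxane synthase gene TBXAS1 by -1.68. NQO1 changed by -1.43, the glutathione transferase gene GSTM3 by -1.52 and the transporter gene ABCC3 by -1.65. SPANXB1, SPANXC and SPANXE, cancer-testis genes of nearly identical sequence whose probes can share signal, changed by -1.38, -1.47 and -1.55. The homeobox genes IRX3 and IRX5, which lie near each other, changed by -1.18 and -1.07.

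The rise of the NF-kB list was set against 3 other explanations. Of 5 leukocyte markers not above background in shCntrl, 0 were above it on both shT7#1 arrays, which argues against RNA of leukocytes, although CD68, HLA-DRA, CD14 and LAPTM5 were above background on all 4 arrays and the source of their signal was not tested. The median of the interferon list lay below that of the NF-kB list by a difference of -1.68 log2 units (95% bootstrap interval over genes -2.64 to -0.73). This was the outcome set against an interferon response to the hairpin as the whole source. A comparison of 2 medians cannot tell whether a response to the hairpin raised both lists, so no conclusion is drawn. The interval measures spread between genes, not between arrays. The 16 members above background on all 4 arrays had a median change of 1.81 (interval 1.14 to 3.19), which argues against an artifact of dim signals. An interferon or related response to the hairpin, its effect on other transcripts, a difference between the cultures and loss of TRPM7 remain open. Only 1 hairpin was compared, and TRPM7 was under the detection floor.

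The fall of luminal markers was weighed in the same way. Of 17 luminal and epithelial markers not above background in shT7#1, 0 were above it on both shCntrl arrays, among them ESR1, FOXA1 and CDH1, which argues against luminal cells in the shCntrl samples. A general fall of epithelial genes stays open, because 15 of 21 detected members (71.4%) had a negative change, between the bounds set for and against it. The biological difference between the groups was not tested separately.

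Fitted log2 changes of the authors' deposited fold table were set against those fitted here, with genes not above background in a group included. Across 948 called genes the excess of the authors' absolute change fell with the signal of the dimmer group (Spearman rho = -0.631 across genes). Its median was 0.549 log2 units for 287 genes whose dimmer group lay under 6, and 0.018 for 346 genes at 8 or above. This is consistent with a difference in the handling of background. The excess was not larger in genes with several probes (median -0.017) than in genes with 1 probe (median 0.122), a difference of -0.139. This argues against the choice of probe as the source of the larger folds. Whether the joining of probes made the authors' folds smaller in genes with several probes was not tested.

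A copy number difference between the cultures was tested as a hypothesis on runs of 50 neighbouring genes among 11966 placed genes. The largest absolute median change of a run was 0.214 log2 units, from NUAK2 to FLVCR1. It lay just under the 95th percentile of 1000 shuffled orders, 0.217 (permutation p = 0.0659). This narrowly met the outcome set beforehand against a copy number difference. A margin this small does not exclude such a difference, so the question stays open.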
